A study of Mus musculus with 8 samples.

How the data were processed

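Total RNA of dissected mouse forebrain and spinal cord was made into libraries with the NEBNext Ultra kit and sequenced on a HiSeq2500, per the labels. Reads were single-end, 50 bases long and unstranded, with a stated target of about 50M reads. The authors deposited a single table of RPKM values (reads per kilobase, scaled to mapped reads) with 1 column for each of the 8 libraries and 36333 rows named by gene symbol. All values were whole multiples of 0.1 RPKM. The labels name the genome builds mm9 and GRCm38, without saying which served which libraries, and the aligner and counting tool are not stated in the labels used here. Because the table holds no counts, the depth of each library is unknown, and no counting interval was computed. The design text also mentions knockout spinal cord, which is not analysed here.

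The gene names did not match the values of the 4 E15.5 columns for part of the rows. Read in the deposited order, wt forebrain at E13.5 and E15.5 correlated across all rows with r = 0.760 on the log2 scale, although r by row was 0.971 between the E13.5 tissues and 0.984 between wt and EED-cKO at E15.5. For 35359 of 36333 names, the name column follows an order in which numbers within names are read as numbers, and the other 974 lie elsewhere. Assigning the same names to the E15.5 columns in alphabetical order, with case and hyphens ignored, raised r to 0.948. Of 5 orders tried, alphabetical order with case ignored gave 0.897, numeric-aware order 0.759, and plain character codes 0.398. In the alphabetical order 13317 names stayed in their row and 23016 moved, and 61 names tied once case and hyphens were ignored. Among moved genes that were tested, r rose from 0.426 to 0.862, against 0.893 for genes with the same row in both orders. Of 36 complex I subunit genes, 21 were below 1 RPKM at E15.5 in the deposited order and 0 in the restored order. Of 370 transfer RNA genes, 232 were at 10 RPKM or more at E15.5 in the deposited order and 0 in the restored order. Genes at 10 RPKM or more in every E13.5 library and at 0 in every E15.5 library numbered 250 before and 30 after. The restored order was used for all results, a choice made after seeing the data, and the deposited order and the use of same-row genes only are given as alternatives.

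Samples were grouped by the labels for age, tissue and genotype. For 16 duplicated symbols, the row with the highest mean was kept. Genes with at least 1 RPKM in at least 2 of the 8 libraries were tested, which left 17022. Values were taken as log2(RPKM + 1), and all 8 libraries were fitted together with 4 group means and 4 residual degrees of freedom in limma 3.58.1 under R 4.3.3 (eBayes with trend, two-sided). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes in a comparison. The 3 comparisons were EED-cKO against wt in E15.5 forebrain, spinal cord against forebrain in E13.5 wt, and E15.5 against E13.5 in wt forebrain. The 35 gene lists held 810 entries, of which 806 matched the table (Ctip2, Hbb-b1, Hbb-b2 and Ahsp did not), and covered Polycomb complexes, Hox genes, regional factors, cell cycle, neural cell types, signalling, imprinted genes and markers of other tissues. They were fixed before the data were examined, as were the groups, tests and named-gene rule. Lists with at least 3 tested members were tested with camera from limma at a preset correlation of 0.01, two-sided, with an estimated correlation beside it, adjusted over all lists in a comparison. A second adjustment of each gene's p was made over the list alone. Spinal-cord-high and forebrain-high sets were genes called between the E13.5 tissues with a log2 change of at least 2 in size. Correlations between comparisons were compared with 100 simulated draws of unchanged groups. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

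The rule named fixed genes, among them Eed, Ezh2, Suz12, Cdkn2a and Mki67, whatever their test. It also named the 8 genes with the highest and the 8 with the lowest log2 change in the knockout comparison, and the 6 highest and 6 lowest in the other comparisons. These had to be called, without overlap between groups, at a mean of at least 2 RPKM in the higher group, and with a symbol that is not a predicted or clone name. From each list described, up to 4 called members with the largest changes could be named, or up to 2 abundant members of a list without calls. Of those, mainly genes whose call held with each library left out were taken up in the text.

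The test was checked on simulated data. Of 100 genes changed by 1 on the log2 scale, 88 were recovered in the knockout and 88 in the regional comparison. Noise was drawn from the spread of each gene pooled over all 4 groups. At a change of 2, 94 and 97 were recovered. Unchanged genes called numbered 10 (5.21% of calls) and 7 (3.65%). The simulation held far fewer changed genes than the data called, and the same spread in every group. These shares therefore need not hold for the knockout calls, as the spread was larger in wt E15.5 forebrain. Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5 RPKM, no filter, a filter at 3 RPKM, median ratio scaling, quantile normalization, a fit of only the 4 libraries compared, eBayes without trend or with the robust option, a log2 change of at least 1, a replicate block, the omission of Hox genes from correlations, and leaving out each library in turn. Replicate pairs correlated with r of 0.993 to 0.994 on the log2 scale, and the median SD between replicates was 0.117 in wt E15.5 forebrain and 0.049 to 0.058 in the other groups.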

Results

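Transcript levels were measured by bulk RNA sequencing in 8 libraries of mouse embryonic central nervous system. The 4 groups held 2 libraries each: wild-type (wt) forebrain and wt spinal cord at embryonic day (E) 13.5, wt forebrain at E15.5, and E15.5 forebrain of EED-cKO embryos, in which Sox1-Cre directs the knockout of Eed. EED is a core subunit of Polycomb repressive complex PRC2, which places a repressive histone mark. Values were RPKM rounded to 0.1 without read counts, so the depth of each library is unknown. The sum of RPKM was 378294 to 397320 in the E13.5 libraries and 761647 to 843296 in the E15.5 libraries. The labels do not say whether replicates came from separate embryos or from pools, so p-values measure only the spread between these samples. With 2 libraries against 2, the smallest two-sided exact permutation p is 0.333, so calls rest on limma, which shares the spread across genes and across all 8 libraries.

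The gene names of the E15.5 columns were used in a restored row order, chosen after seeing the data. A gene whose E15.5 row was reassigned is called moved, and such genes are marked in places. A gene without a mark need not have the same row in both orders. Changes between the E13.5 tissues carry no marks, although Nkx2-1, for example, is moved. Of 17022 tested genes, 7596 were moved and 9426 had the same row in both orders. Every group value is a mean ± SD of n = 2, and changes are log2 fold changes of RPKM + 1 with their standard error (SE), which understate the fold of genes with low values. Reads were unstranded, so overlapping antisense transcripts cannot be separated, and values of near-identical gene copies are uncertain. Counts adjusted over the list alone were the same as the counts over all genes wherever they are not given.

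The comparison of EED-cKO with wt E15.5 forebrain asked which transcripts differ when EED is removed from neural cells. Eed itself (GRCm38 chromosome 7, 89954654 to 89980976) was at 10 and 10.6 RPKM in the EED-cKO libraries, against 25.8 and 27.9 in wt E15.5 forebrain, 31.2 and 34 in wt E13.5 forebrain, and 19.1 and 17 in wt E13.5 spinal cord. It fell in EED-cKO forebrain (log2 −1.30 ± 0.085 SE, limma adjusted p = 8.7e-05). Ezh2, which encodes the PRC2 methyltransferase, fell from 66.2 ± 3.18 to 29.9 ± 0.424 RPKM (log2 −1.12 ± 0.069). Suz12, another core subunit, was at 24.1 ± 1.77 RPKM in EED-cKO and 29.4 ± 1.27 in wt (log2 −0.27 ± 0.078, limma adjusted p = 0.0254), a call lost without EED-cKO replicate 1 (adjusted p = 0.138), without wt E15.5 replicate 1 (0.0755), and without spinal cord replicate 1 (0.0503) or 2 (0.0503). Of 12 tested PRC2 components, 3 rose and 5 fell, and of 20 PRC1 components, 4 rose and 2 fell. The PRC2 genes that rose, Jarid2, Aebp2 and Ezh1, lost their calls without EED-cKO replicate 1 (log2 0.48, 0.38 and 0.35) and without replicate 2 (0.53, 0.36 and 0.25). So did Mtf2, which fell (log2 −0.50 and −0.30). Ezh1 also lost its call without either wt E15.5 or either spinal cord library. Mtf2 lost its call without wt E15.5 replicate 1 and without any of the E13.5 libraries. Neither list was called by camera (adjusted p = 0.304 and 0.858). The PRC2 list had a median of 0.14, a mean of −0.16 and a downward test, and its median was −0.12 after quantile normalization. For PRC1 the median was 0.08 (−0.02 after quantile normalization), with a downward test. Bmi1 rose by 0.63 ± 0.071 and Phc2 fell by 0.64 (SE 0.091) on the log2 scale.

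In EED-cKO forebrain, limma called 7987 of 17022 genes, with 5149 higher and 2838 lower, so that 64.5% of calls were higher. Median ratio scaling gave 4043 higher and 4240 lower (48.8% higher), and quantile normalization gave 3540 higher and 4314 lower (45.1% higher). The median log2 change of all genes was 0.08, and −0.05 after quantile normalization. Among genes changed by at least 1 on the log2 scale, 1116 were higher and 194 were lower. The values of the groups did not overlap for 70.3% of genes, where chance gives 33.3% for any single gene. All genes share the same split of libraries, so a shift of whole libraries separates many of them at once. The median log2 value of tested genes was 3.78 and 3.83 in EED-cKO, and 3.66 and 3.55 in wt. The cell cycle inhibitor gene Cdkn2a rose from 0.1 to 65.2 ± 1.77 RPKM (log2 5.91 ± 0.086, limma adjusted p = 3.8e-07). Lamp5, a lysosome-associated membrane protein gene, rose from 0.55 ± 0.212 to 52.6 ± 1.06 RPKM (log2 5.12 ± 0.12). Vax2, a homeobox gene of the ventral eye, was listed at 0 in both wt libraries and at 31.5 and 29.9 RPKM in EED-cKO. The largest decrease was in the adult beta-globin gene Hbb-bt, from 395.4 and 547.4 RPKM to 5.9 and 8.1 (log2 −5.88 ± 0.21), while its neighbour Hbb-bs was not called (log2 0.57, limma adjusted p = 0.0556). With only the 4 libraries compared, the count of called genes was 4777. The fit of all 8 libraries gives every group the same spread, which may understate that of this comparison. The median SD between replicates was 0.117 in wt E15.5 forebrain and 0.049 to 0.058 in the other groups.

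**Figure D1:**
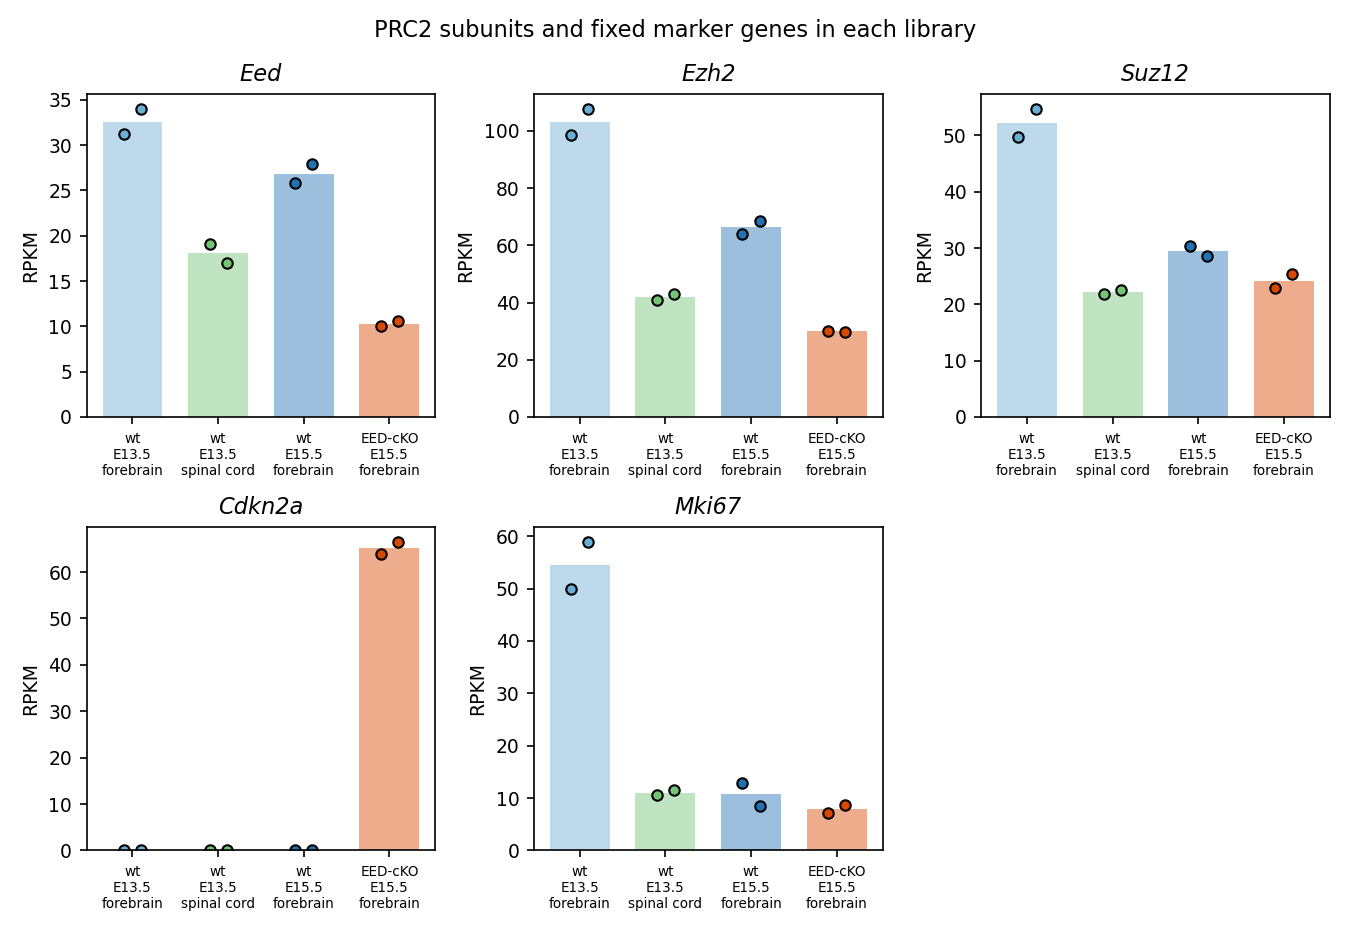
RPKM of Eed, Ezh2, Suz12, Cdkn2a and Mki67 in the 8 libraries, with points for libraries and bars for the mean of each group. Cdkn2a is at most at 0.1 RPKM outside the EED-cKO libraries, where it is at 63.9 and 66.4.

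Hox genes, which pattern the body axis behind the forebrain, rose in all 3 lists of paralogue groups in EED-cKO forebrain. Of the tested genes, 10 of 11 in groups 1 to 4 rose, 14 of 15 in groups 5 to 9, and all 11 in groups 10 to 13, and none of the others fell. The filter shaped these counts. Hoxd12, at 0 in both EED-cKO libraries and at 0.9 and 0 RPKM in spinal cord, was not tested. Hoxb13, at 0 in every wt library, was tested through the EED-cKO libraries alone. Camera called the 3 lists (adjusted p = 9.4e-07, 6.2e-10 and 0.00012), and none of these calls held with an estimated correlation (adjusted p = 0.241, 0.164 and 0.369). Hoxc12 was listed at 0 in both wt E15.5 libraries and at 74.8 and 64.9 RPKM in EED-cKO. Hoxc13 was at 48.4 and 40.5 RPKM and Hoxb13 at 37.3 and 34.4, again against 0 in both wt libraries. Hoxc9, at 24.2 and 22.7 RPKM, and Hoxa7, at 22.7 and 20.4, were also listed at 0 in wt. Hoxc10 was at 53.5 and 46.4 RPKM against 0 in both wt libraries (log2 5.67 ± 1.41, limma adjusted p = 0.0151). Its SE takes in the spread of the spinal cord libraries (45.2 and 0.2 RPKM), which this comparison does not use. The call was lost without either EED-cKO library (log2 5.57 without replicate 1 and 5.77 without replicate 2) or either wt E15.5 library (5.67 without each). In groups 1 to 4, Hoxb3 rose from 0.35 ± 0.0707 to 11.2 ± 0.283 RPKM (log2 3.18 ± 0.11). All the Hox genes named here are moved, and of the 39 Hox genes few, among them Hoxb1 and Hoxd1, had the same row in both orders.

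**Figure D2:**
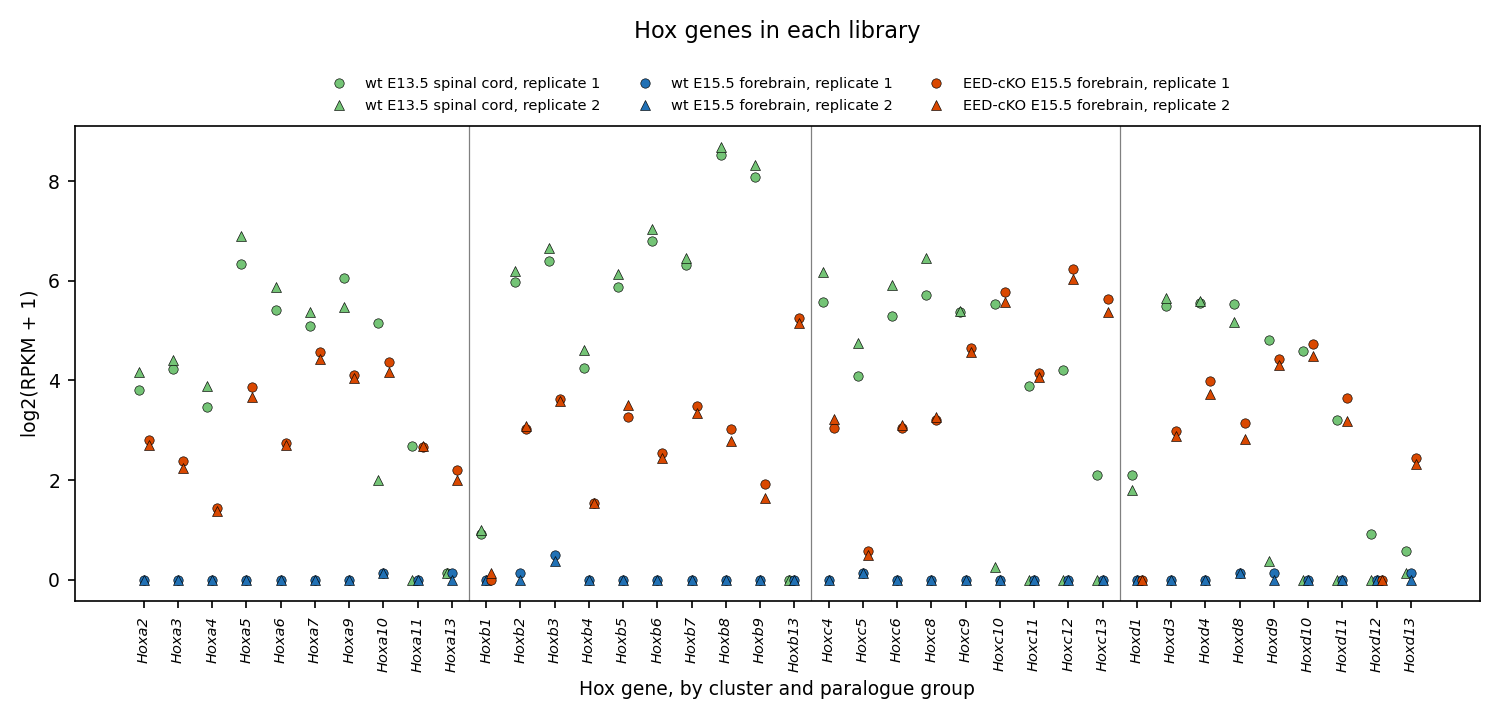
Level of Hox genes as log2(RPKM + 1) (vertical axis), ordered by cluster and paralogue group, in wt E13.5 spinal cord and in EED-cKO and wt E15.5 forebrain, with points for libraries. The sum over groups 10 to 13 is 300.8 and 260.8 RPKM in the EED-cKO libraries (replicates 1 and 2), 152.5 and 3.4 in wt spinal cord, and 0.3 and 0.1 in wt E15.5 forebrain. RPKM values at E13.5 and E15.5 are not on a common scale.

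Transcription factors of the forebrain fell as a list in EED-cKO, while those of the spinal cord and hindbrain rose. The rise was not particular to spinal cord and hindbrain factors (median log2 1.52), as factors of other lineages, described below, had a median of 1.49. Of 41 forebrain factors, 24 fell and 8 rose (camera adjusted p = 1.4e-07, and adjusted p = 0.164 with an estimated correlation). Eomes, a factor of cortical intermediate progenitors, fell from 33.2 ± 0.283 to 3.1 RPKM (log2 −3.06 ± 0.092). Six6 (log2 2.99 ± 0.13), Otx2 (1.60 ± 0.17) and Barhl2 (1.43 ± 0.11), which act in eye and diencephalon, rose. Of 46 spinal cord and hindbrain factors, 36 rose and 3 fell, or 38 and 5 adjusted over the list alone (camera adjusted p = 3.0e-09, and adjusted p = 0.164 with an estimated correlation). Pax2 rose from 0 and 0.1 RPKM to 20 and 16.8, Tal1 from 2.3 ± 1.41 to 52.8 ± 4.17 (log2 4.09 ± 0.27), and Gata3 from 2.65 ± 2.62 to 31.9 ± 2.19 (log2 3.39 ± 0.53). Lbx1 was listed at 0 in both wt libraries and at 9.5 and 7.6 RPKM in EED-cKO.

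Genes of cortical glutamatergic neurons fell, with 12 of 18 lower and 2 higher (camera adjusted p = 1.1e-06, and adjusted p = 0.241 with an estimated correlation). Neurod6 (moved) fell from 374 ± 35.2 to 13.7 ± 1.27 RPKM (log2 −4.67 ± 0.14), and Fezf2, a factor of subcerebral projection neurons, from 55.5 ± 5.09 to 9.15 ± 0.354 (log2 −2.47 ± 0.086). Neurod2 (moved) fell from 172 ± 0.636 to 14.3 ± 0.99 RPKM (log2 −3.50 ± 0.13), a direction that was reversed under the deposited row order. Tiam2 (log2 −3.80 ± 0.16), Sla (−3.24 ± 0.16) and Mpped1 (−3.15 ± 0.10) were also among the genes with the largest decreases. Slc17a6 (moved, log2 1.33 ± 0.11) and Reln (1.08 ± 0.10) rose. Of 17 GABAergic genes, 9 fell and 5 rose (10 and 5 adjusted over the list alone), and the camera call (adjusted p = 0.0109) was lost with an estimated correlation (adjusted p = 0.432), after quantile normalization (0.0816) and without wt E15.5 replicate 1 (0.0877). Lhx6 (log2 −2.29 ± 0.076), Dlx1 (−1.56 ± 0.17) and Dlx2 (−1.51 ± 0.14), factors of forebrain interneurons, fell, while Gad1, which encodes a GABA-synthesizing enzyme, rose (0.72 ± 0.077). Of 12 motor and cholinergic neuron genes, 9 rose (12 adjusted over the list alone), none fell, and the list was called (camera adjusted p = 0.00023, and adjusted p = 0.189 with an estimated correlation). Mnx1, a motor neuron factor, was listed at 0 in wt and at 6.3 and 5.2 RPKM in EED-cKO, and Gfra1 rose by 1.70 ± 0.095 on the log2 scale. Pan-neuronal genes were not called as a list (10 of 31 higher, 4 lower, camera adjusted p = 0.373), with Snap25 higher (log2 0.73 ± 0.084) and Tubb3 lower (−0.66 ± 0.10).

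Cell cycle and DNA replication genes fell in EED-cKO forebrain, with 41 of 55 lower and 2 higher, or 44 and 2 adjusted over the list alone (camera adjusted p = 1.0e-14, and adjusted p = 0.241 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell from 57.1 ± 1.91 to 25.4 ± 4.1 RPKM (log2 −1.15 ± 0.12), Ube2c by 1.11 (SE 0.11) and Ccna2 by 1.07 (SE 0.085) on the log2 scale. The members that rose were Ccnd1, a cyclin of the G1 phase, from 29.6 ± 1.48 to 126 ± 2.26 RPKM (log2 2.06 ± 0.059), and Ccnd3 (log2 0.68 ± 0.066). Mki67 was at 7.95 ± 1.06 RPKM in EED-cKO and 10.7 ± 3.11 in wt (limma adjusted p = 0.146), and it was called without wt E15.5 replicate 2 (adjusted p = 0.0245). Of 7 CDK inhibitor genes, 4 rose and 1 fell, without a call for the list (camera adjusted p = 0.0868). Besides Cdkn2a, Cdkn2b at the same locus rose from 0.5 ± 0.141 to 17.1 ± 0.283 RPKM (log2 3.60 ± 0.10) and Cdkn1a from 24.1 ± 3.04 to 70.6 ± 0.707 (log2 1.52 ± 0.094), while Cdkn1b fell by 0.69 (SE 0.070) on the log2 scale. Of 22 p53 target genes, 11 rose and 2 fell, and the camera call (adjusted p = 0.0102) was lost with an estimated correlation (adjusted p = 0.164) and without wt E15.5 replicate 1 (0.0502). The p53 targets Phlda3 (log2 2.27 ± 0.11), Pmaip1 (2.13 ± 0.11), Eda2r (1.98 ± 0.10) and Sesn2 (1.94 ± 0.082) rose. Neural progenitor genes went both ways, with 11 of 29 higher and 12 lower, or 11 and 13 adjusted over the list alone (camera adjusted p = 0.128). Hopx (log2 1.22 ± 0.14) and Vim (0.96 ± 0.086) rose, and Sox1 fell by 1.09 (SE 0.13) on the log2 scale.

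Genes of other lineages, of mesenchyme, choroid plexus, vessels and immune cells also rose in EED-cKO forebrain. Transcription factors of other lineages were higher for 53 of 57 tested and lower for 2, or 55 and 2 adjusted over the list alone (camera adjusted p = 1.8e-16, and adjusted p = 0.164 with an estimated correlation). The list held 74 members. A member below 1 RPKM in every wt library was tested only if both EED-cKO libraries reached 1 RPKM. The filter thus left out silent members that did not respond, and the counts and the list test favour a rise. This holds for every list with such members. Hand2, a factor of heart and limb, was listed at 0 in both wt libraries and at 22.8 RPKM in both EED-cKO libraries, and Barx1, a stomach and tooth factor, rose from 0.05 ± 0.0707 to 19.2 ± 3.04 RPKM (log2 4.26 ± 0.15). Tfap2c (log2 −1.18 ± 0.090) was among the members that fell. All 24 genes of meninges and mesenchyme rose, with Twist1 from 2.25 ± 0.354 to 25.6 ± 0.424 RPKM (log2 3.04 ± 0.15) and the moved collagen genes Col1a1 (log2 2.37 ± 0.25) and Col1a2 (54 ± 13.4 to 218 ± 42.7 RPKM). EED-cKO replicate 2 was higher than replicate 1 for Col1a1 (207.4 and 125 RPKM), and for the muscle gene Acta1 (49.4 and 3.9), while Twist1 was at 25.3 and 25.9. The mesenchyme list was called (camera adjusted p = 7.8e-10, and adjusted p = 0.164 with an estimated correlation). All 17 choroid plexus genes rose, among them Msx1 (log2 1.81 ± 0.22), Sostdc1 (1.75 ± 0.16) and Clic6 (1.64 ± 0.14), and the list was called (camera adjusted p = 1.8e-07, and adjusted p = 0.183 with an estimated correlation). Markers of vessels and immune cells rose by less. In endothelium 19 of 22 genes rose (camera adjusted p = 0.00023, and adjusted p = 0.369 with an estimated correlation), with Kdr at 0.96 ± 0.14. In pericytes 9 of 12 rose, or 10 adjusted over the list alone (adjusted p = 0.0015, and adjusted p = 0.241 with an estimated correlation), with Pdgfrb from 12.3 and 8.4 RPKM to 20 and 22.7. In microglia and macrophages 18 of 22 rose (adjusted p = 0.00012, and adjusted p = 0.358 with an estimated correlation), with Mrc1 at 1.34 ± 0.12. No member of these 3 lists fell by limma.

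**Figure D3:**
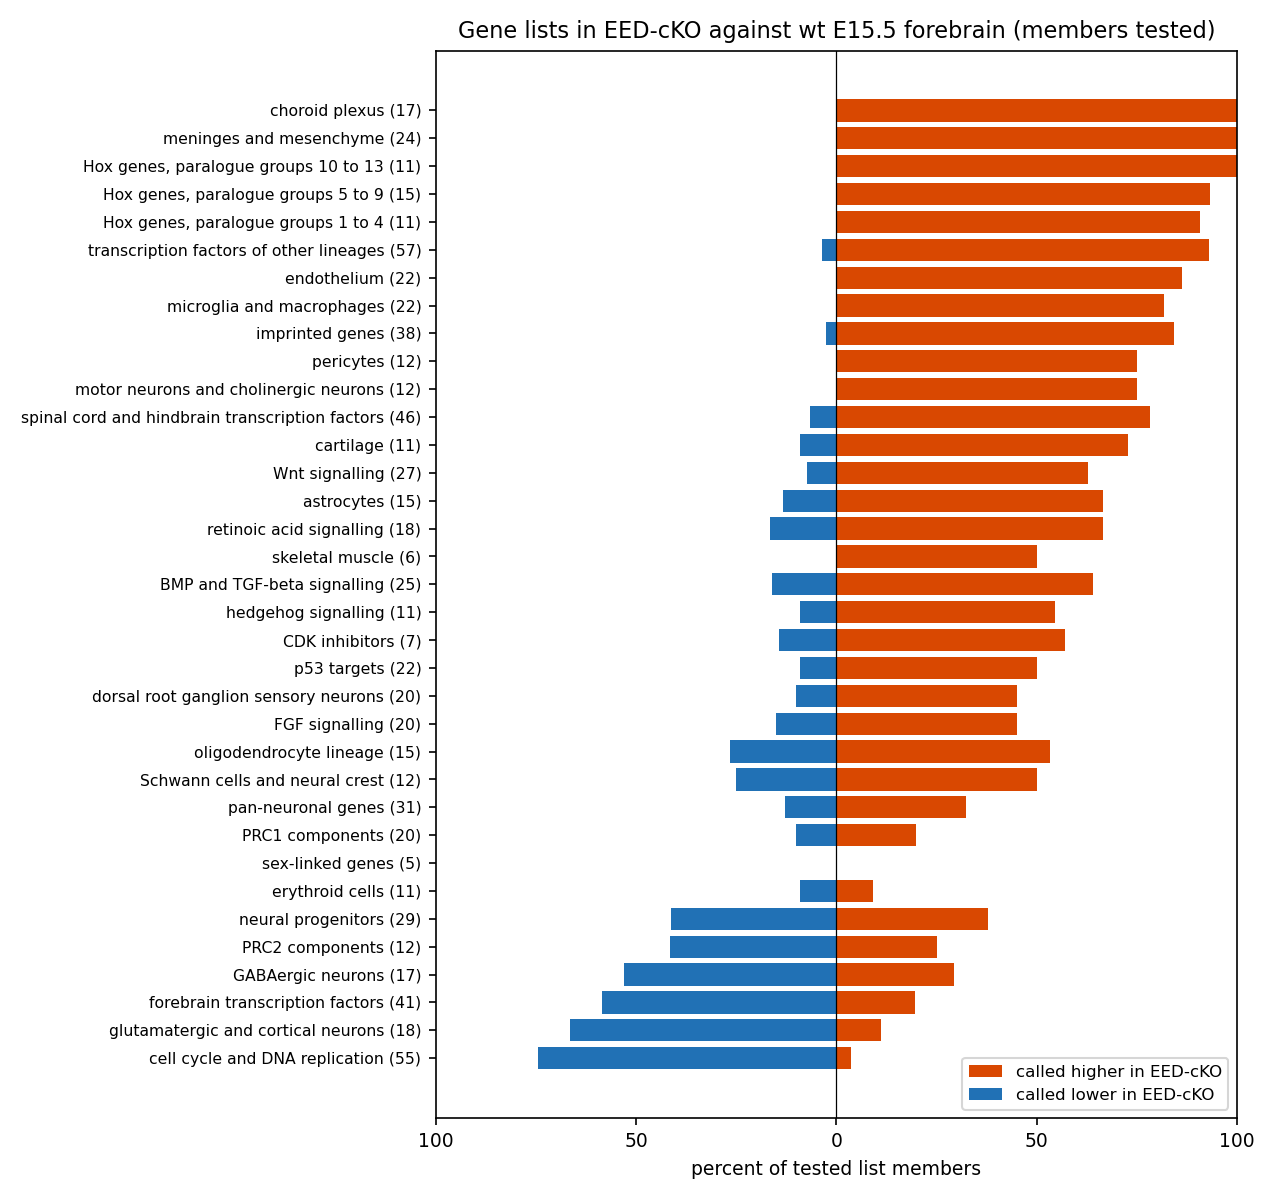
Percent of the tested members of each fixed gene list that were called higher (right) or lower (left) in EED-cKO against wt E15.5 forebrain. All 24 genes of meninges and mesenchyme were higher, and 41 of 55 cell cycle genes were lower.

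The comparison of wt E13.5 spinal cord with wt E13.5 forebrain gave the regional difference against which the knockout effect can be set. Limma called 7784 of 17022 genes, 3714 higher and 4070 lower in spinal cord, with 904 and 748 changed by at least 1 on the log2 scale. Hoxb8 rose from 0.05 ± 0.0707 to 388 ± 29.1 RPKM (log2 8.53 ± 0.11) and Hoxb9 to 293 ± 35.3 (8.13 ± 0.13). Hoxb6 was listed at 0 in both forebrain libraries and at 110.7 and 130.2 RPKM in spinal cord. Hoxa5 (80.3 and 117.7) and Hoxb7 (78.3 and 86.9) were likewise listed at 0 in forebrain, and Hoxb3 rose by 6.39 ± 0.11 on the log2 scale. All 11 Hox genes of groups 1 to 4 and 14 of 15 of groups 5 to 9 were higher (camera adjusted p = 2.7e-12 and 1.3e-15, and adjusted p = 0.174 and 0.153 with an estimated correlation). Groups 10 to 13 were not called as a list (adjusted p = 0.0721), with 1 of 11 genes higher. Several of them were seen in spinal cord replicate 1 almost alone, where Hoxc10 was at 45.2 RPKM against 0.2 in replicate 2, and Hoxc12 at 17.4 against 0. Ttr, the transthyretin gene of the choroid plexus, fell from 193 ± 1.77 to 0.2 ± 0.141 RPKM (log2 −7.34 ± 0.13). Eomes (log2 −5.86 ± 0.092), Emx1 (−5.81 ± 0.16) and Nkx2-1 (−5.73 ± 0.13), regional factors of the forebrain, were lower. Dlx1as (−6.18 ± 0.17), which overlaps Dlx1 on the other strand, was also lower. Of 41 forebrain factors, 39 were lower, or 40 adjusted over the list alone (camera adjusted p = 7.9e-24, and adjusted p = 0.125 with an estimated correlation). Of 46 spinal cord and hindbrain factors, 33 were higher and 4 lower, or 35 and 5 adjusted over the list alone (adjusted p = 5.9e-11, and adjusted p = 0.174 with an estimated correlation), with Tlx3 at 5.91 ± 0.10 and Pax2 at 5.27 ± 0.11.

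Proliferation and maturation genes differed between the E13.5 regions. All 55 cell cycle genes were lower in spinal cord (camera adjusted p = 7.2e-29, and adjusted p = 0.203 with an estimated correlation), with Ccnd2 lower by 3.50 on the log2 scale (log2 −3.50 ± 0.10) and Mki67 at 11.1 ± 0.778 RPKM against 54.4 ± 6.22. Of 29 progenitor genes, 21 were lower and 4 higher, or 22 and 4 adjusted over the list alone (adjusted p = 1.1e-06, and adjusted p = 0.153 with an estimated correlation), with Sox1 at −3.01 ± 0.13. All 31 pan-neuronal genes were higher (adjusted p = 1.6e-13, and adjusted p = 0.298 with an estimated correlation), and the neurofilament genes Nefl (4.22 ± 0.12) and Nefm (4.21 ± 0.13) were among them. Of 12 motor neuron genes, 11 were higher (adjusted p = 1.3e-08, and adjusted p = 0.153 with an estimated correlation), with Isl2 at 4.12 ± 0.21. Markers of dorsal root ganglia and Schwann cells, which a dissection could hold, were also higher in spinal cord. Bulk values do not tell such tissue from the cord itself. In dorsal root ganglion neurons 19 of 20 genes were higher (adjusted p = 1.1e-12, and adjusted p = 0.231 with an estimated correlation). In Schwann cells and neural crest 10 of 12 were higher and 1 lower (adjusted p = 8.1e-05, and adjusted p = 0.298 with an estimated correlation). Tbr1 (log2 −5.18 ± 0.079), Dlx2 (−5.70 ± 0.14) and Dlx1 (−5.63 ± 0.17) fell, Dlx1 with the overlap named above. Of the 18 glutamatergic genes 12 were lower and 4 higher (adjusted p = 0.0200, and adjusted p = 0.572 with an estimated correlation), and of the 17 GABAergic genes 10 were lower and 5 higher (adjusted p = 0.0093, and adjusted p = 0.489 with an estimated correlation). The GABAergic call was lost without wt E15.5 replicate 1 (0.0780) or 2 (0.0782). Ezh2 (log2 −1.28 ± 0.069), Suz12 (−1.20 ± 0.078) and Eed (−0.82 ± 0.085) were lower in spinal cord, as were 8 of the 12 PRC2 genes, with 3 higher. The PRC2 call (adjusted p = 0.0273) was lost with an estimated correlation (adjusted p = 0.242). Cdkn2a was at 0.1 RPKM or less in every E13.5 library and was not called (limma adjusted p = 0.558).

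Signalling and accessory cell lists separated the E13.5 regions further. Retinoic acid genes were higher in spinal cord for 11 of 18 and lower for 3 (camera adjusted p = 0.0020, and adjusted p = 0.298 with an estimated correlation), with Crabp1 at 2.80 ± 0.15 and Meis1 at 2.25 ± 0.099. Of 11 hedgehog genes, 6 were lower and none was higher (adjusted p = 0.0144, and adjusted p = 0.489 with an estimated correlation), with Gli3 at −2.10 ± 0.14. Of 27 Wnt genes, 15 were lower and 5 higher, or 16 and 5 adjusted over the list alone (adjusted p = 0.0183, and adjusted p = 0.338 with an estimated correlation), with Wnt8b at −2.99 ± 0.13. Choroid plexus genes were lower for 11 of 17 and higher for 1 (adjusted p = 0.00054, and adjusted p = 0.334 with an estimated correlation), with Clic6 at −3.18 ± 0.14. Microglia genes were higher for 10 of 22, none was lower (adjusted p = 0.0035, and adjusted p = 0.519 with an estimated correlation), and C1qb was at 0.65 ± 0.12. Erythroid genes were lower for 8 of 11 (adjusted p = 0.0233, and adjusted p = 0.572 with an estimated correlation), a call lost without forebrain replicate 2 (0.0894). The other lists were not called, with the lowest adjusted p, 0.0720, for meninges and mesenchyme (12 of 24 higher and 4 lower, or 13 and 5 adjusted over the list alone).

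The knockout effect was then set against the regional difference, which shares no library with it. Across 17022 genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.382 and Spearman rho = 0.365. In 100 simulated draws of unchanged groups, r lay between −0.079 and 0.079. The draws took noise independently for each gene, so this range is too narrow for genes that vary together. The regional difference also covers proliferation, with all 55 cell cycle genes lower in spinal cord. In EED-cKO 41 of them fell and 2 rose, so r does not measure regional identity alone. Without the Hox genes r was 0.346. Of 184 genes higher in spinal cord by at least 2 on the log2 scale, 131 rose and 8 fell in EED-cKO forebrain, with a median of 0.93. Of 163 genes higher in forebrain, 103 fell and 28 rose, with a median of −0.64. Among the other 16675 genes, 29.9% rose and 16.4% fell. These genes were not matched to the 2 regional sets by their level in wt forebrain. A gene near 0 there can rise but hardly fall. The counts therefore do not tell a regional shift from a broader rise of silent genes. Factors of other lineages, with a median of 0 between the regions, had a median of 1.49 in EED-cKO. Camera called both regional sets (adjusted p = 1.9e-16 and 5.2e-15, and adjusted p = 0.0404 for each with an estimated correlation). Without Hox genes, 108 of 160 spinal-cord-high genes rose, and camera with an estimated correlation gave p = 0.0795. The calls overlapped by direction, with 1901 genes higher in both comparisons where independent lists would share 1123, and 1530 lower in both against 679. In opposite directions, 722 genes were higher in EED-cKO and lower in spinal cord against 1231, and 235 the other way against 619. Both comparisons use the same estimate of spread for each gene. Genes of low spread thus tend to be called in both, and the numbers for independent lists do not allow for this.

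**Figure D4:**
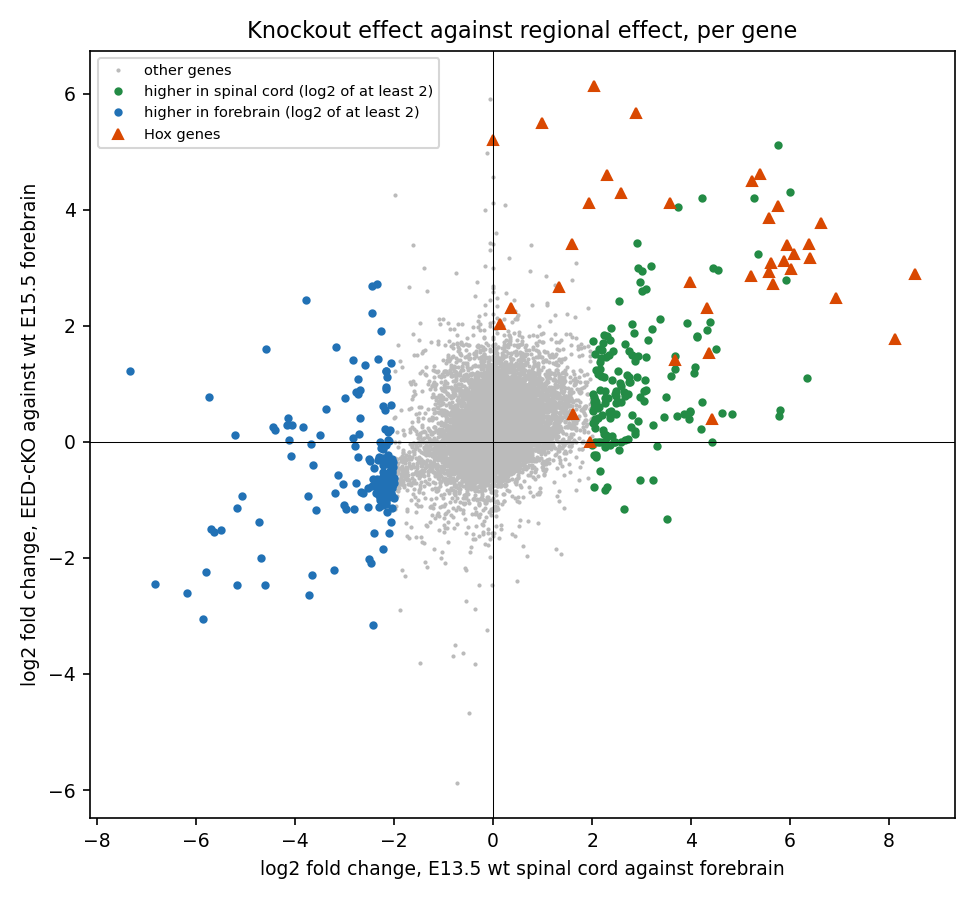
Log2 fold change of each of the 17022 tested genes in EED-cKO against wt E15.5 forebrain (vertical axis) and in wt E13.5 spinal cord against forebrain (horizontal axis), with colours for genes higher in spinal cord, genes higher in forebrain and Hox genes. The correlation across genes is r = 0.382.

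The comparison of wt forebrain at E15.5 with E13.5 addressed change with age, but the values of the ages differed widely in scale, and the labels do not say whether they were processed alike, so age and any difference in processing cannot be told apart. Gapdh was at 1514 ± 144 RPKM at E15.5 and 27.2 ± 0.283 at E13.5, and the median of 72 ribosomal protein genes was 967 and 110 RPKM. Limma called 13117 genes, 10646 higher and 2471 lower (81.2% higher), where median ratio scaling gave 6132 higher and 5955 lower (50.7%) and quantile normalization 5979 and 6049 (49.7%). The median log2 change of all genes was 0.52. The embryonic globin genes Hbb-y, from 2879 ± 932 to 3.95 ± 0.636 RPKM (log2 −9.15 ± 0.21), and Hba-x (log2 −6.87 ± 0.23) were lower at E15.5. H2afz (moved), a histone variant gene, was at 1.45 ± 0.0707 RPKM at E15.5 and 456 ± 31.5 at E13.5 (log2 −7.54 ± 0.12). Snurf was higher (log2 6.46 ± 0.28), as was Rpl21 (moved, 5.63 ± 0.098), which has near-identical copies, while Rpl37rt (−7.32 ± 0.13) and Rpl32l (−6.30 ± 0.10), both moved, were lower in the restored order and higher in the deposited order. Tmsb15l (moved, 36.2 and 52 RPKM) and Rnu6 (moved, 46.2 and 38.2) were listed at 0 in both E13.5 libraries, and AF357359 (99.6 and 131.6 RPKM at E13.5) in both E15.5 libraries. Ptgds, which encodes prostaglandin D synthase, was higher, from 2.15 ± 0.212 to 274 ± 16.5 RPKM (log2 6.45 ± 0.11). Mki67 fell by 2.26 (SE 0.18) on the log2 scale. Cell cycle genes were lower for 45 of 55 and higher for 3 (camera adjusted p = 2.9e-27, and adjusted p = 0.399 with an estimated correlation). Progenitor genes were lower for 21 of 29 and higher for 5, or 21 and 6 adjusted over the list alone (adjusted p = 7.3e-11, and adjusted p = 0.217 with an estimated correlation). Pan-neuronal genes were higher for 30 of 31 and lower for 1 (adjusted p = 0.0026, and adjusted p = 0.799 with an estimated correlation). Ezh2 (log2 −0.63 ± 0.069) and Suz12 (−0.81 ± 0.078) were lower. Eed was lower at E15.5 (log2 −0.27 ± 0.085, limma adjusted p = 0.0214), a call lost without E13.5 forebrain replicate 2 (0.124) or wt E15.5 replicate 1 (0.0877), and Cdkn2a was not called (0.486). Hedgehog genes were lower for 10 of 11 (adjusted p = 2.0e-08, and adjusted p = 0.399 with an estimated correlation). Factors of other lineages (8 of 57 higher, 22 lower, or 8 and 21 adjusted over the list alone), of spinal cord and hindbrain (4 of 46 higher, 14 lower, or 2 and 8) and of forebrain (12 of 41 higher, 20 lower) were called downward (adjusted p = 1.0e-07, 1.5e-06 and 2.7e-05, and adjusted p = 0.399 for each with an estimated correlation). Across genes, the knockout and age effects correlated with r = −0.0922, where the shared wt E15.5 libraries alone gave a simulated mean of −0.503. This r was −0.00290 after quantile normalization and −0.171 without wt E15.5 replicate 1. The covariance of the effects was −0.0537 against a simulated −0.00987. The draws held noise alone, with the same spread in every group. The simulated r is therefore no measure for an r that also holds real effects. The median SD between replicates was 0.117 in wt E15.5 forebrain and 0.049 to 0.058 in the other groups. The simulated covariance may thus understate what the shared libraries give.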

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

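The deposited row order, the restriction to same-row genes and the crossed replicate block were chosen after seeing the data, and the other alternatives were fixed beforehand. Eed stayed lower in EED-cKO forebrain under each alternative run, with log2 changes from −1.41 to −1.25, and the regional sets kept their directions and, at the preset correlation, their calls. With an estimated correlation, spinal-cord-high genes gave p = 0.0338, but 0.0795 without Hox genes and 0.0591 with same-row genes. For named genes and lists, 8522 values kept their call and direction, 519 lost it, 7 gained it and 18 reversed. Without 1 library, the call of 30 of 192 named genes changed in the knockout comparison, of 30 of 189 in the regional comparison, and of 1 of 18 (Eed) in the age comparison. An arm left with 1 library was tested with the spread of the other groups. Depth is unknown, and values rounded to 0.1 RPKM limit what can be said of genes near 0.

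Called genes numbered 7987 in the knockout, 7784 in the regional and 13117 in the age comparison. With only the 4 libraries compared (2 residual degrees of freedom), the counts were 4777, 8582 and 12020, so the regional count did not fall. The fit of all 8 libraries gives every group the same spread. The median SD between replicates was 0.117 in wt E15.5 forebrain and 0.049 to 0.058 in the other groups. The pooled spread may thus understate that of the knockout comparison. Requiring a log2 change of at least 1 left 1310, 1652 and 5499, and testing only same-row genes left 4929, 4792 and 7209, since fewer genes can pass. Leaving out each library gave 4922 to 9606, 5205 to 9320 and 11768 to 13010. List calls, 22, 19 and 13, were 0 in each comparison with an estimated correlation, 8 for age under the deposited order, and 19 to 23, 18 to 21 and 10 to 14 without each library. The knockout and regional effects (r = 0.382) correlated with 0.364 at a pseudocount of 0.1, 0.411 with the filter at 3 RPKM, 0.297 in the deposited order, 0.346 without Hox genes and 0.354 to 0.393 without each library. The knockout and age effects (r = −0.0922) correlated with −0.00290 after quantile normalization and −0.171 to −0.0582 without each library. The cause was not tested where none is given.

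Besides the list calls lost with an estimated correlation, knockout calls were lost in the deposited order for astrocytes (adjusted p = 0.188), pericytes (0.127), microglia (0.0519) and dorsal root ganglion neurons (0.0580), and with same-row genes for astrocytes (0.0572), cartilage (0.206), BMP and TGF-beta (0.109) and Wnt genes (0.106). The regional PRC2 call was lost with same-row genes (0.177). The cause was not tested.

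In the deposited order, knockout changes reversed for these moved genes, in log2: Neurod2 0.53, Cdc25c 0.11, Gtse1 0.12, Gpr17 0.069, Sox10 0.15, Cd83 −0.069, Tmem119 −0.35, Sox5 1.31, Nog 0.13, Wnt9a −1.18, Wnt7b 1.05, Wnt7a 1.01, Stra6 −0.15 and Ndn 0.39. The age changes of Rpl37rt (2.51) and Rpl32l (3.56) reversed as well, since another row then carries each name. After quantile normalization, Fabp7 in the knockout comparison (0.041) and the age change of a gene not described here (−0.28) reversed, and the cause was not tested.

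The labels state no pairing by replicate number. Deviations from the group mean correlated across genes with r = −0.124 between wt and EED-cKO at E15.5 and 0.211 between the E13.5 tissues (0.105 without sex-linked genes). Replicate number went with sex in both E13.5 tissues, with Xist at 0 in replicate 1 and at 75 and 83.5 RPKM in replicate 2. With replicate number within age as a block, 6657 knockout, 6702 regional and 12718 age genes were called, and 8045 knockout genes with the EED-cKO numbers crossed.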

Other observations

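The tests of the row order and the ages, blood RNA, neural share, meningeal tissue and Hox paralogue groups were chosen after the result was seen. Imprinted genes rose in EED-cKO forebrain, with 32 of 38 higher and 1 lower (camera adjusted p = 1.2e-07, and adjusted p = 0.164 with an estimated correlation). Zdbf2 rose from 5.4 ± 1.56 to 19.9 ± 0.354 RPKM (log2 1.73 ± 0.16), Igf2, a fetal growth factor gene, by 1.69 ± 0.19, and the moved genes Peg10 and Peg3 by 1.74 ± 0.16 and 1.67 ± 0.17. Igf2 and Dcn are also in the list of meninges and mesenchyme, all of whose 24 members rose. Genes of BMP and TGF-beta signalling were higher for 16 of 25 and lower for 4, or 18 and 4 adjusted over the list alone (adjusted p = 0.0082, and adjusted p = 0.164 with an estimated correlation). Tgfb2 rose (log2 1.38 ± 0.10) and Id2 fell from 281 ± 29.2 to 50.3 ± 1.7 RPKM (−2.46 ± 0.086). Wnt genes were higher for 17 of 27 and lower for 2 (adjusted p = 0.0045, and adjusted p = 0.241 with an estimated correlation). The hedgehog (6 of 11 higher, 7 adjusted over the list alone, 1 lower), retinoic acid (12 of 18 higher, 3 lower) and FGF (9 of 20 higher, 3 lower) lists were not called (adjusted p = 0.123, 0.126 and 0.373). Gli1 and Ptch1, readouts of hedgehog signalling, rose by 1.09 ± 0.14 and 0.98 ± 0.13, and Crabp1 by 2.03 ± 0.15.

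Astrocyte genes were higher for 10 of 15 and lower for 2, or 11 and 2 adjusted over the list alone, and the call (camera adjusted p = 0.0124) was lost with an estimated correlation (adjusted p = 0.435). Gfap (log2 1.67 ± 0.088) and Gjb6 (1.44 ± 0.13) rose. The oligodendrocyte list (8 of 15 higher, 4 lower, or 9 and 5 adjusted over the list alone) was not called (adjusted p = 0.373), with Pdgfra at 0.94 ± 0.12. Dorsal root ganglion genes were higher for 9 of 20 and lower for 2, or 11 and 2 adjusted over the list alone (adjusted p = 0.0179, and adjusted p = 0.529 with an estimated correlation), a call lost without wt E15.5 replicate 1 (0.0558), with Pou4f2 at 2.60 ± 0.18. Cartilage genes were higher for 8 of 11 and lower for 1 (adjusted p = 0.0146, and adjusted p = 0.435 with an estimated correlation), a call lost without wt E15.5 replicate 2 (0.0594). The Schwann cell (6 of 12 higher, 3 lower, or 7 and 3 adjusted over the list alone), erythroid (1 of 11 higher, 1 lower) and muscle (3 of 6 higher) lists were not called (adjusted p = 0.304, 0.594 and 0.163), the erythroid list with a median of 0.31 and a mean of −0.17. Only 6 of 23 muscle genes passed the filter. Others, such as Actc1 (25.4 RPKM) and Ckm (14.6), reached 1 RPKM in EED-cKO replicate 2 alone, so the muscle list test leaves them out. Of the higher muscle genes, Tnnt1 (2 and 9.3 RPKM in EED-cKO replicates 1 and 2, against 0.9 and 1.2) and Tnnc1 (2.8 and 8.1, against 1.5 and 1.9) lost their calls without any 1 of the E13.5 libraries and without either wt E15.5 library (limma adjusted p = 0.174 and 0.146 for Tnnt1, 0.143 and 0.107 for Tnnc1), and Tnnt1 without EED-cKO replicate 2 (0.0874). None of 5 sex-linked genes was called by limma, and 0 had an unadjusted p under 0.05. Their SE takes in the E13.5 groups, where Xist was at 0 and 75 RPKM in forebrain and at 0 and 83.5 in spinal cord. The test could therefore hardly call a difference in these genes at E15.5.

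In the age comparison, further lists were called with a downward test, none with an estimated correlation: cartilage (1 of 11 higher, 7 lower, or 1 and 9 adjusted over the list alone, adjusted p = 4.3e-05, and 0.437 estimated), Wnt (8 of 27 higher, 10 lower, 0.0038 and 0.399), erythroid (5 of 11 higher, 5 lower, 0.0113 and 0.737), meninges and mesenchyme (7 of 24 higher, 8 lower, or 6 and 8 adjusted over the list alone, 0.0212 and 0.704) and dorsal root ganglion neurons (4 of 20 higher, 4 lower, or 4 and 3 adjusted over the list alone, 0.0498 and 0.799). Camera compares a list with all other genes, and the median change of all tested genes was 0.52. The mesenchyme list had a median of 0.060 and a mean of 0.16 under a downward test, and its median was −0.55 with median ratio scaling and −0.52 after quantile normalization. Hox groups 5 to 9 (adjusted p = 0.0290, and 0.704 estimated) had no called gene among 15 and sums of 0.25 RPKM at both ages, so that their test reflects the rise of other genes alone.

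The E15.5 values of many gene names matched other genes at E13.5. A difference between the ages or in their processing would affect genes with the same row in both orders alike, but these correlated with r = 0.893 between the ages, against 0.426 for moved genes in the deposited order. Another row order of the E15.5 columns may account for the mismatch, since moved genes reached 0.862 in the alphabetical order. That the submitters sorted these columns separately stays a hypothesis.

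Hbb-bt fell from 395.4 and 547.4 RPKM in wt E15.5 forebrain to 5.9 and 8.1 in EED-cKO. Less blood RNA in the EED-cKO libraries would lower the other adult globin genes too, but the median log2 change of Hba-a1, Hba-a2 and Hbb-bs was 0.32, and Hbb-bs went from 3159 and 4340 RPKM to 5109 and 5902. A strain variant may be carried with the targeted Eed allele, as Hbb-bt lies on the same chromosome (7, 103812524 to 103813923). Large calls were not more frequent within 20 Mb of Eed (15 of 245 genes against 1251 of 15627 elsewhere, odds ratio 0.749, 95% interval 0.411 to 1.27, Fisher's exact p = 0.341), which leaves this open. Reads shared between the near-identical beta-globin copies and an effect of EED loss itself stay untested.

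All 24 genes of meninges and mesenchyme rose in EED-cKO forebrain, of which 24 were at 1 RPKM or more in wt E15.5 forebrain and 8 are also in another list. A lower share of neural cells that raised the markers of all other types alike would give like medians. The median log2 change was higher than that of endothelium by 0.959 (two-sided permutation p = 1e-05, the smallest that 100000 draws can give), and than that of choroid plexus by 0.266 (permutation p = 0.111). The permutation treats genes as independent, which markers of the same cell type are not. An equal rise of all other types leaves the excess over endothelium unexplained. A lower neural share may still be part of the rise, as endothelium (19 of 22), pericyte (9 of 12) and microglia genes (18 of 22) rose and none fell. EED-cKO replicate 2 stood apart by its muscle genes (Acta1 at 49.4 RPKM against 3.9 in replicate 1), while mesenchyme genes were high in both libraries (Dcn 107.8 and 105.6 in replicates 1 and 2, Twist1 25.9 and 25.3, Col1a1 125 and 207.4). More meningeal tissue in the EED-cKO dissections may contribute, but 8 of the 8 most abundant members in wt, such as Igf2 (117 to 374 RPKM), Col3a1 (59.6 to 210.1), Col1a2 (54 to 218) and Dcn (37.5 to 107), rose like every other member, so their count decides nothing. Altered expression within EED-cKO neural cells is untested. It, more meningeal tissue and a lower neural share as part of the rise stay open, as bulk values do not locate the transcripts.

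In EED-cKO forebrain, Hox genes of higher paralogue groups may reach higher levels. The Spearman correlation of group number and mean RPKM over 39 Hox genes was 0.445 (two-sided permutation within clusters, p = 0.00919), against −0.363 in wt spinal cord (p = 0.0223), where it was −0.258 in replicate 1 and −0.512 in replicate 2. The sums over groups 1 to 4, 5 to 9 and 10 to 13 were 60.2, 154.8 and 280.8 RPKM in EED-cKO and 383.4, 1421.3 and 77.95 in spinal cord. The last value is a mean of 152.5 in replicate 1 and 3.4 in replicate 2, against 300.8 and 260.8 in the EED-cKO libraries. The sum of RPKM over all genes was higher in every E15.5 library than in every E13.5 library. Levels in EED-cKO forebrain and wt spinal cord are therefore not on a common scale, and only the order of paralogue groups within each is compared. The hypothesis rests on the restored row order, as the deposited order gave 0.163 (permutation p = 0.374) in EED-cKO.

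Of 23 skeletal muscle genes, 22 were highest in EED-cKO replicate 2, with Acta1 at 49.4 RPKM against 3.9 in replicate 1, Actc1 at 25.4 against 0.3, and Ckm at 14.6 against 0.2. Replicate 1 of both E13.5 tissues had Xist at 0 and Kdm5d at 10.9 (forebrain) and 10.8 RPKM (spinal cord), and replicate 2 had Xist at 75 and 83.5 and Kdm5d at 0. The E15.5 libraries had Xist from 33 to 73.6 RPKM and Kdm5d at 0.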
